A study of Homo sapiens with 6 samples.

How the data were processed

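Chromatin immunoprecipitation with anti-Flag beads was followed by sequencing in 293T cells that carried Flag-RBMX or Flag-RPA1 and had been in camptothecin for 24 hours, per the labels. The 4 precipitations gave a peak list each, called per sample, and the 2 input samples were not analysed here. The replicate number 2 is in the labels, and the number 1 was given in accession order and names a sample without pairing it. The genome build was hg38, also written GRCh38, per the submitters' processing notes, which also name Bowtie2, MACS, MACS2 2.2.4 and deepTools 3.4.1.

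Replicate 1 peaks were called with MACS 1.4.2 with no control file, a p-value cutoff of 1e-05, at most 1 tag per position and a background taken from the precipitated library itself over up to 10000 bp, per the file headers. The deposited tags are whole-number counts within the peak. The deposited score is minus 10 times the log10 of the p-value, and it is converted here to −log10. It reached 310 on that scale for 2 RBMX peaks and 1 RPA1 peak, the maximum of these lists. The deposited fold is a ratio of tags to that background. Tags were 50 bp long and were extended to 200 bp.

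Replicate 2 peaks were called with MACS2 2.2.4 with the input library named as control, a p-value cutoff of 1e-12, at most 1 tag per position and the local background switched off, per the file headers. Tags were 150 bp long and the extension was 200 bp. The controls had 6393212 tags for RBMX and 4693961 for RPA1, and the larger library was scaled to the smaller. The deposited signal is the pileup of tags at the summit after that scaling, and dividing it by the scale returned whole tags, within 0.02 of a tag, for 100% of the summits of both lists. The deposited −log10 p-values and q-values are those of the peak caller; the header says that q would be given as minus 1, but the column holds values of at least 8.7. The deposited fold is a ratio of pileup plus 1 to the background plus 1. That divisor was the same for every peak of a list, at 1.474 for RBMX and 1.348 for RPA1 (coefficients of variation 0.01101% and 0.01325%), which equals the genome-wide mean of the scaled libraries plus 1. The input therefore set a single level for the genome, and copy number, mappability or other regional differences that an input shows were not removed from these peaks. In neither replicate was a peak compared with an input at its own position.

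Positions were compared with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and drawn with matplotlib 3.10.9. Peaks overlapped when they shared at least 1 bp. Comparisons between replicate numbers used the chromosomes and the mitochondrial genome, since other sequences are named differently in the 2 sets of files. For a one-sided permutation test, the peaks of a list were placed 10000 times at random on the same sequence, keeping their widths, between the first and the last peak of any list on it; assembly gaps were not left out, which lowers the random overlap. The short unplaced sequences leave little room for placement, which raises it. Sequence beyond the outermost peaks of a chromosome was not reached, which lowers the random share near chromosome ends. The test was tested on simulated lists. With no shared peaks it gave p under 0.05 in 1 of 100 simulations of 229 peaks in replicate 1 and 4 of 100 of 431 peaks in replicate 2, and with 10% shared in 100 of 100 in both. Unshared peaks were simulated by the same random placement as in the test, on the chromosomes alone. Clustering of peaks was not simulated, so the error rate for clustered lists is unknown. Intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only. Benjamini-Hochberg adjustment was over the tests of each family.

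Gene positions came from a RefSeq table of GRCh38.p14 with 58994 genes placed on the chromosomes and the mitochondrial genome. It states gene bodies and no exons, strands, centromeres or repeats, so the planned classes by soft-masked repeat, tandem period, short motif, centromere and short arm, and by exon, intron or transcription start, were not analysed here. In their place the gene classes by midpoint were within 1 kb of a gene boundary, elsewhere inside a gene and between genes. Gene-free stretches of at least 1 Mb were added after the data were examined, as were the class of outermost sequence (start within 20 kb of the chromosome start or beyond the last annotated gene) and pseudogenes. A chromosome end was taken as the last annotated gene or peak. The genes named were fixed before the data were examined. They are the 10 peaks of largest fold in each list, the 10 merged regions held by most lists ranked by their smallest fold, the genes of fixed lists (common fragile sites, ribosomal RNA, small nuclear RNA, histone, tRNA, pericentromeric and duplicated families, coding minisatellites and abundantly transcribed genes) that a peak overlaps, and RBMX, RBMXL1 and RPA1. Copies of RBMX were added after their values were seen. The count and test of the common fragile site genes in RPA1 replicate 1 are not reported here.

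RBMX and RPA1 were compared with Fisher's exact test per class within each replicate number, and folds of shared and unshared peaks of a list with a permutation test of 100000 resamples. The exact McNemar test compared partners of the same peaks. Alternatives were another overlap rule, a stricter threshold (−log10 p of at least 10 in replicate 1 and −log10 q of at least 5 in replicate 2), the upper part of each list by fold, other placements, other class limits and leaving out a replicate number.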

Results

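The series profiled where 2 Flag-tagged human proteins were found on DNA in 293T cells, a human embryonic kidney line that is easily transfected. RBMX is an RNA-binding protein of the hnRNP family, and RPA1 is the large subunit of replication protein A, the complex that coats single-stranded DNA. Cells were transfected with Flag-RBMX or with Flag-RPA1 and kept for 24 hours in camptothecin, an inhibitor of topoisomerase I. Chromatin was precipitated through the Flag tag and sequenced. The title of the series places RBMX on repetitive DNA together with RPA, so the comparisons below ask how far the peaks of the 2 proteins coincide and in which parts of the genome they lie. All samples had camptothecin, and no comparison with untreated cells was made.

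There were 6 samples, 4 of them precipitations (2 per protein) and 2 of them inputs. A peak list was analysed for each precipitation. Whether the second precipitation of each protein came from a separate culture is not stated in the labels, and peaks within a list are not replicates. The p-values below therefore describe these lists. In replicate 1 the RBMX library had 20199680 tags after filtering and 258 peaks, and the RPA1 library had 20089972 tags and 360 peaks. In replicate 2 the RBMX library had 6664290 tags and 598 peaks, and the RPA1 library had 6889249 tags and 527 peaks. The peaks covered 285.3 kb and 381.9 kb in replicate 1, and 319.5 kb and 296.9 kb in replicate 2, for RBMX and RPA1 respectively. Their median width was 888.5 bp and 884.5 bp in replicate 1 and 332 bp and 383 bp in replicate 2. Fold enrichments are the authors' own values, each relative to the background of its own list.

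RBMX and RPA1 peaks coincided at many positions within each replicate. In replicate 2, 456 of 598 RBMX peaks (76.3%, exact 95% interval 72.6% to 79.6%) overlapped an RPA1 peak, and 461 of 527 RPA1 peaks (87.5%) overlapped an RBMX peak. In replicate 1 the corresponding values were 107 of 258 RBMX peaks (41.5%, interval 35.4% to 47.7%) and 109 of 360 RPA1 peaks (30.3%). Random placement of each RBMX peak on its own sequence, short unplaced and alternate sequences included, gave an overlap of 11.66% in replicate 2 and 4.62% in replicate 1. On the chromosomes alone, 317 of 431 RBMX peaks (73.5%) overlapped in replicate 2 and 86 of 229 (37.6%) in replicate 1, against 0.05% under random placement in both. Shifting each of all 598 and 258 RBMX peaks by up to 50 kb gave random overlaps of 31.11% in replicate 2 and 10.01% in replicate 1. Shifted peaks were held within the outermost peaks of their sequence, which raises these values on short unplaced sequences. They are therefore to be read against the shares of all peaks and not those on the chromosomes. All 6 one-sided permutation p-values were 0.0001, the smallest that 10000 placements can give. Over all peaks the share was 34.8 percentage points higher in replicate 2 than in replicate 1 (Fisher's exact test, two-sided, p = 3.397e-22). At a stricter threshold, which removed no replicate 2 peaks, 52 of 65 RBMX peaks of replicate 1 overlapped an RPA1 peak. In the 50% of each list with the larger fold the shares were 64.3% in replicate 1 and 76.3% in replicate 2, and among the 100 chromosome peaks of largest fold, 65 and 95 RBMX peaks overlapped an RPA1 peak.

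**Figure D1:**
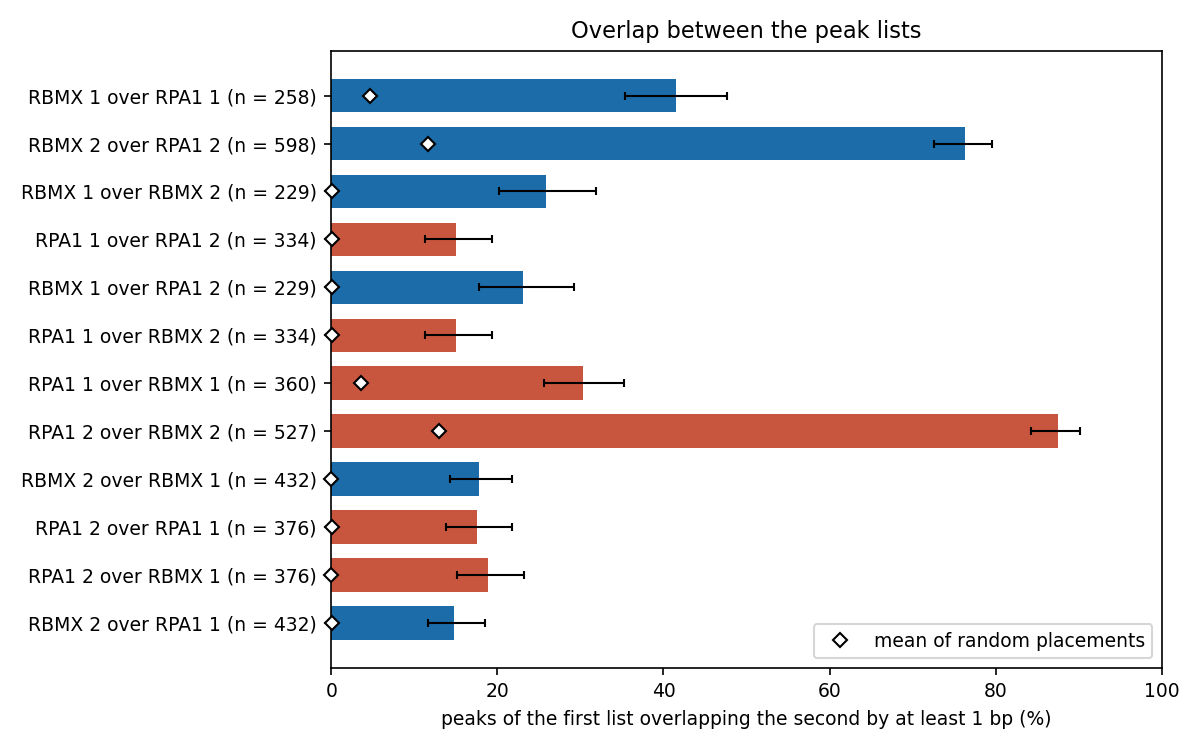
Share of the peaks of the first-named list (in %, horizontal axis) that overlapped a peak of the second-named list, for all 12 ordered pairs of the 4 lists, with exact 95% intervals as error bars and the mean of random placements as diamonds. The highest shares, 76.3% and 87.5%, were those between RBMX and RPA1 in replicate 2.

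The 2 replicates of each protein had fewer peaks in common than the 2 proteins of a replicate. On the chromosomes and the mitochondrial genome, 59 of 229 RBMX peaks of replicate 1 (25.8%, interval 20.2% to 31.9%) overlapped an RBMX peak of replicate 2, and 50 of 334 RPA1 peaks (15%, interval 11.3% to 19.3%) overlapped an RPA1 peak of replicate 2. Random placement gave 0.04% and 0.03%, and shifting each peak by up to 50 kb gave 5.3% and 3.09%; all 4 permutation p-values were 0.0001. Among the same 229 RBMX peaks of replicate 1, 86 (37.6%) overlapped an RPA1 peak of replicate 1, against 59 that overlapped an RBMX peak of replicate 2 (exact McNemar test, two-sided, p = 0.000142). For the 334 RPA1 peaks of replicate 1 the counts were 87 and 50 (exact McNemar test, p = 9.335e-09). In replicate 2 they were 317 and 77 of 431 RBMX peaks (exact McNemar test, p = 5.429e-62) and 326 and 66 of 375 RPA1 peaks (exact McNemar test, p = 8.998e-73). In the lists of the other replicate number, RBMX peaks of replicate 2 overlapped RBMX more often than RPA1 (77 against 64 peaks, exact McNemar test, p = 0.007197). This rests on 17 peaks with only an RBMX partner against 4 with only an RPA1 partner. The 17 include peaks over RBMX, RBMXL1, RBMXP2 and RBMXP5, and the comparison without these was not tested. The difference between the same and the other protein did not pass the test for RBMX replicate 1 (59 against 53, exact McNemar test, p = 0.07031), RPA1 replicate 1 (50 against 50, exact McNemar test, p = 1.0) and RPA1 replicate 2 (66 against 71, exact McNemar test, p = 0.3323), where the same protein is given first. The peak caller, its threshold, the use of a local background, the number of tags and the tag length differed between the replicate numbers. Processing and replicate therefore cannot be told apart. Among replicate 1 chromosome peaks past a stricter threshold, 77.4% of 53 RBMX peaks and 66.1% of 59 RPA1 peaks were found in the other replicate, against 86.8% and 86.4% in the other protein. The difference then no longer passed the test for RBMX (exact McNemar test, p = 0.302) and still did for RPA1 (exact McNemar test, p = 0.00754). A required overlap of 50% of both peaks left 10.9% and 7.8% in common between replicates, and leaving out gene-free stretches left 14.2% and 8.2%.

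Merging the 4 lists gave 859 regions, of which 44 were held by all 4 lists, 12 by 3, 278 by 2 and 525 by 1. Of the 278 regions held by 2 lists, 235 were held by RBMX and RPA1 of replicate 2 and 37 by RBMX and RPA1 of replicate 1. Gene-free stretches of at least 1 Mb, taken in place of centromeres, whose coordinates were not used here, contained 25 of the 44 regions held by all 4 lists (56.8%). Ranked by their smallest fold, 7 of the first 10 such regions lay in these stretches. They were 26603583 to 26604305, 25919951 to 25920397, 26885192 to 26885959 and 26619453 to 26620378 on chromosome 17, 50555822 to 50556348 on chromosome 4, 93470211 to 93471011 on chromosome 3 and 60310659 to 60311225 on chromosome 7. The first of these had a fold of 40.8 in RBMX replicate 1, 34.9 in RPA1 replicate 1, 65.8 in RBMX replicate 2 and 58.4 in RPA1 replicate 2. The other regions among the 10 were 633829 to 634609 on chromosome 1, over the mitochondrial pseudogenes MTATP6P1 and MTCO3P12, 34571515 to 34573522 on chromosome 16, which lay 138401 bp from the nearest gene, and 43231709 to 43232750 on chromosome 17, which lay 440 bp from CCDC200.

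Of the 10 peaks of largest fold per list, 7 in each replicate 1 list, 6 in RBMX replicate 2 and 4 in RPA1 replicate 2 were also found in the other 3 lists. The position 93470310 to 93470849 on chromosome 3 had the largest fold of RBMX replicate 2, at 260.4, and the matching peak had the largest fold of RPA1 replicate 2, at 202. In replicate 1 the largest folds, 46.1 for RBMX and 48.0 for RPA1, were both at the chromosome 4 position given above. Among these 10, 6 in each replicate 1 list and 7 in each replicate 2 list lay in gene-free stretches of at least 1 Mb. In both replicate 2 lists, ranks 2 and 4 were a pair of peaks at 125178798 to 125183236 on chromosome 1, with folds of 223.3 and 188.8 for RBMX and 182.2 and 148.9 for RPA1. Peaks at 143202378, 143212431 and 143214193 on chromosome 1 and at 46388544 on chromosome 16 also ranked in the first 10 of both replicate 2 lists, and a peak at 34582084 on chromosome 16 in that of RBMX. The whole mitochondrial genome, positions 1 to 16569, was a single peak in both replicate 2 lists, with a fold of 188.2 for RBMX and the third largest fold of the list for RPA1, and had no peak in replicate 1. EEF1A1, which encodes a translation elongation factor, had the third largest fold of RBMX replicate 2, at 195.3. TBC1D5 on chromosome 3 had a peak at 17401765 to 17402788 with a fold of 24.9 in RBMX replicate 1 and at 17401545 to 17402626 with a fold of 21.3 in RPA1 replicate 1, and an RBMX peak of replicate 2 overlapped it. RBMXP2 and RBMXP5 were among the first 10 of RBMX replicate 1. NPAS4, which encodes a transcription factor, and LOC124904138 were among the first 10 of RPA1 replicate 1, and both also had a peak in RBMX replicate 1. The remaining peaks, in RPA1 replicate 2, were placed at the ends of chromosomes 12 and Y of the genome build, with folds of 125.1 and 125.6. Whether their reads came from these copies or from similar sequence elsewhere was not analysed here.

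Within each list, peaks that the other protein shared had the larger fold. The median fold of shared against unshared peaks was 9.63 against 5.29 for RBMX and 9.41 against 5.62 for RPA1 in replicate 1. In replicate 2 it was 20.53 against 13.70 for RBMX and 17.93 against 13.13 for RPA1. Two-sided permutation p-values, adjusted over the 4 lists, were 1e-05 for the first 3 lists named, the smallest that 100000 resamples can give, and 0.00054 for RPA1 replicate 2.

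Peaks of both proteins were concentrated in gene-free stretches. These 32 stretches add up to 216 Mb; 8 and 9 of them held a peak of RBMX and RPA1 in replicate 1, and 17 and 16 in replicate 2. They held 184 of 431 chromosome peaks of RBMX replicate 2 (42.7%) and 158 of 375 of RPA1 replicate 2 (42.1%), against 6.74% and 6.98% under random placement. In replicate 1 they held 46 of 229 RBMX peaks (20.1%) and 42 of 334 RPA1 peaks (12.6%), against 6.42% and 6.45%. All 4 permutation p-values were 0.0001 (0.0003 adjusted over 68 tests of classes). The class of gene-free stretches was added after the data were examined. No peak was compared with an input at its own position, so these shares do not separate binding from copy number or mappability. At a stricter threshold the replicate 1 shares were 58.5% of 53 RBMX peaks and 49.2% of 59 RPA1 peaks. The stretch from 121571889 to 143299517 on chromosome 1 held the most peaks, 62 of RBMX and 55 of RPA1 in replicate 2. Unplaced or alternate sequence held 27.8% of 598 RBMX peaks and 28.7% of 527 RPA1 peaks in replicate 2. In replicate 1 it held 29 of 258 (11.2%) and 26 of 360 (7.2%), which rose to 18.5% and 20.3% at a stricter threshold. Within 500 kb of a chromosome end lay 28 RBMX peaks (6.5%) and 31 RPA1 peaks (8.3%) of replicate 2, against 0.27% and 0.26% under random placement (permutation p = 0.0001 each). In replicate 1, 1 RBMX peak (permutation p = 0.4142) and 5 RPA1 peaks (permutation p = 0.0017) lay there. Random placement did not go beyond the outermost peaks of a chromosome, so parts of the end windows could not be reached. On chromosome 1 the first peak started at 629426, outside the window of 500 kb. This lowers the random shares and p-values for chromosome ends, at 500 kb and at 2 Mb. Whether the replicate 1 counts exceed a placement over whole windows was not tested. At a stricter threshold the RPA1 share was 1.7%, close to the 1.5% of all peaks, but with 1 of 59 peaks it no longer passed the test (permutation p = 0.1573), and within 2 Mb of an end the RBMX share of replicate 1 was 5.7% and passed the test (permutation p = 0.0002).

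**Figure D2:**
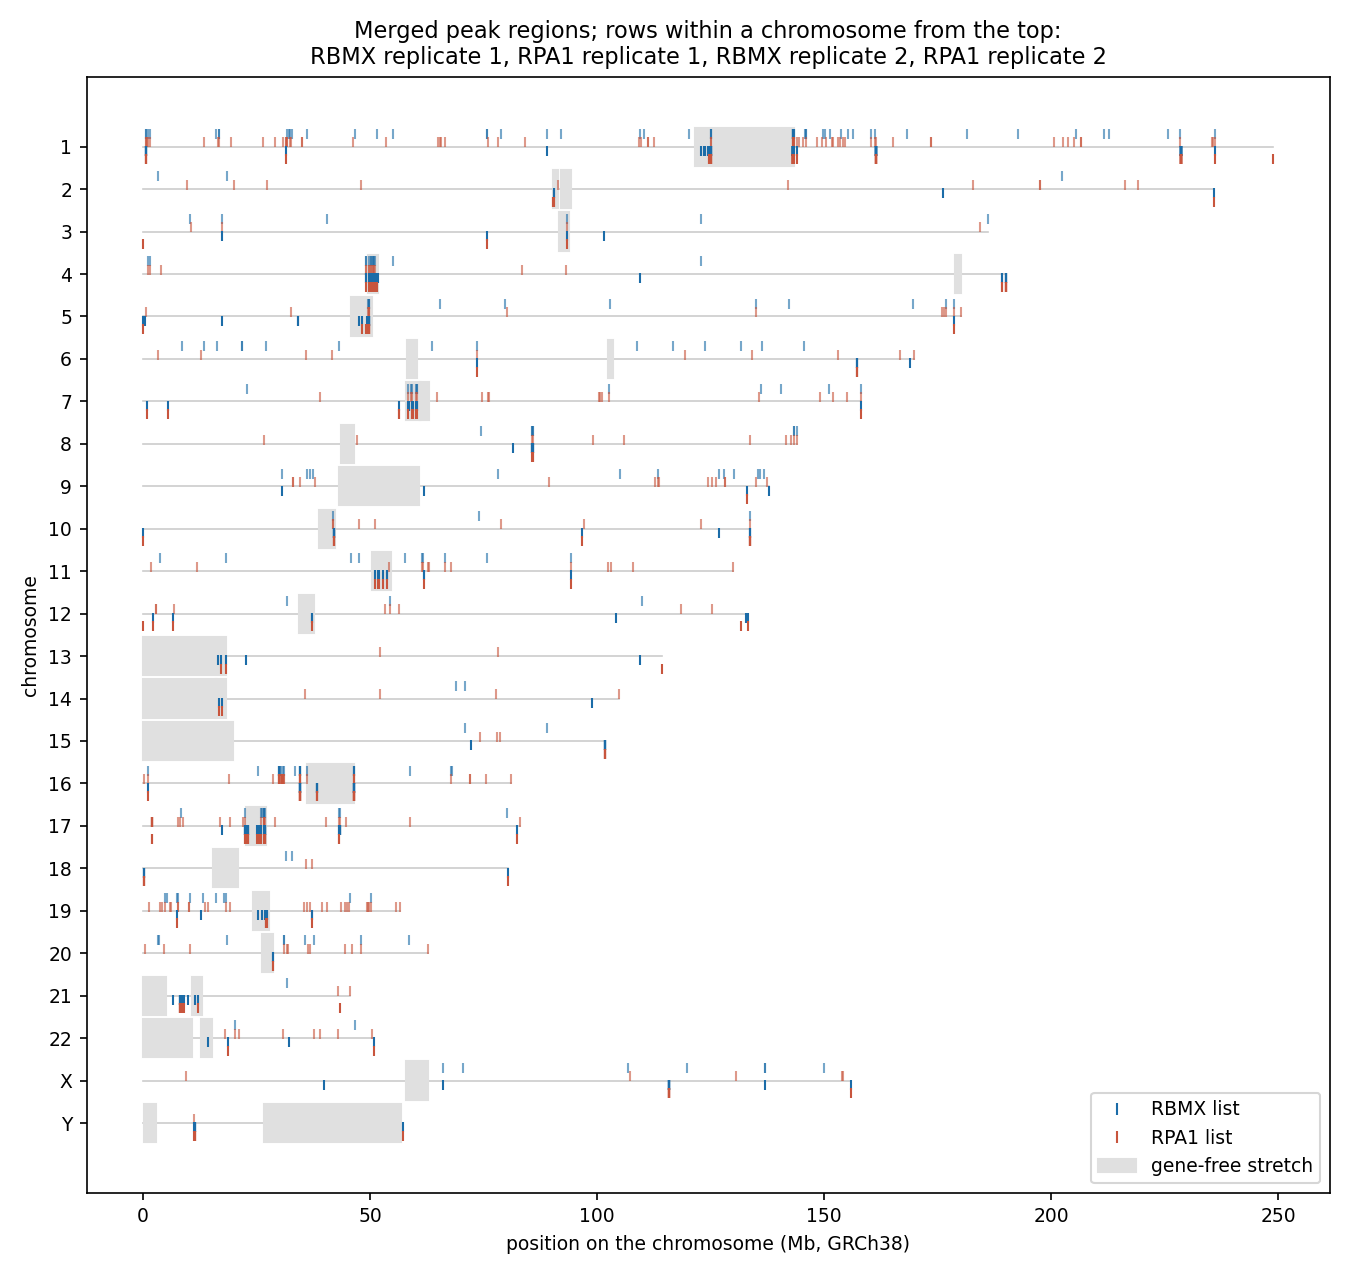
Positions of the merged peak regions on each chromosome (horizontal axis, Mb of GRCh38) in 4 rows per chromosome, RBMX and RPA1 of replicate 1 above RBMX and RPA1 of replicate 2, with gene-free stretches in grey. Replicate 2 regions gather in the grey stretches, such as that of chromosome 1 with 62 RBMX and 55 RPA1 peaks, while replicate 1 regions are also spread along the arms.

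Peaks of both proteins also lay near gene boundaries. In replicate 1, 83 of 229 RBMX peaks (36.2%) and 146 of 334 RPA1 peaks (43.7%) had their midpoint within 1 kb of a gene boundary, 5.3 and 6.0 times the random value. In replicate 2 the shares were 25.5% and 22.4%, or 3.8 and 3.4 times the random value. Each of these 4 permutation p-values was 0.0001. The difference between the replicate numbers was not tested. At a stricter threshold the share in replicate 1 was 13.2% of 53 RBMX peaks (permutation p = 0.066) and 11.9% of 59 RPA1 peaks (permutation p = 0.1212), so the call was lost. Elsewhere inside genes lay 23.1% and 24.3% of the peaks in replicate 1 and 8.8% and 8.5% in replicate 2, for RBMX and RPA1, against 51.48%, 52.09%, 49.96% and 49.6% under random placement (permutation p for fewer = 0.0001 each). Between genes lay 65.7% and 69.1% in replicate 2, against 43.39% and 43.84% (permutation p = 0.0001 each), and 40.6% and 32.0% in replicate 1, against 41.64% (permutation p for fewer = 0.4078) and 40.57% (permutation p for fewer = 0.0006). The replicate 1 shares turned to 75.5% and 67.8% at a stricter threshold, above random placement (permutation p = 0.0001 each).

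**Figure D3:**
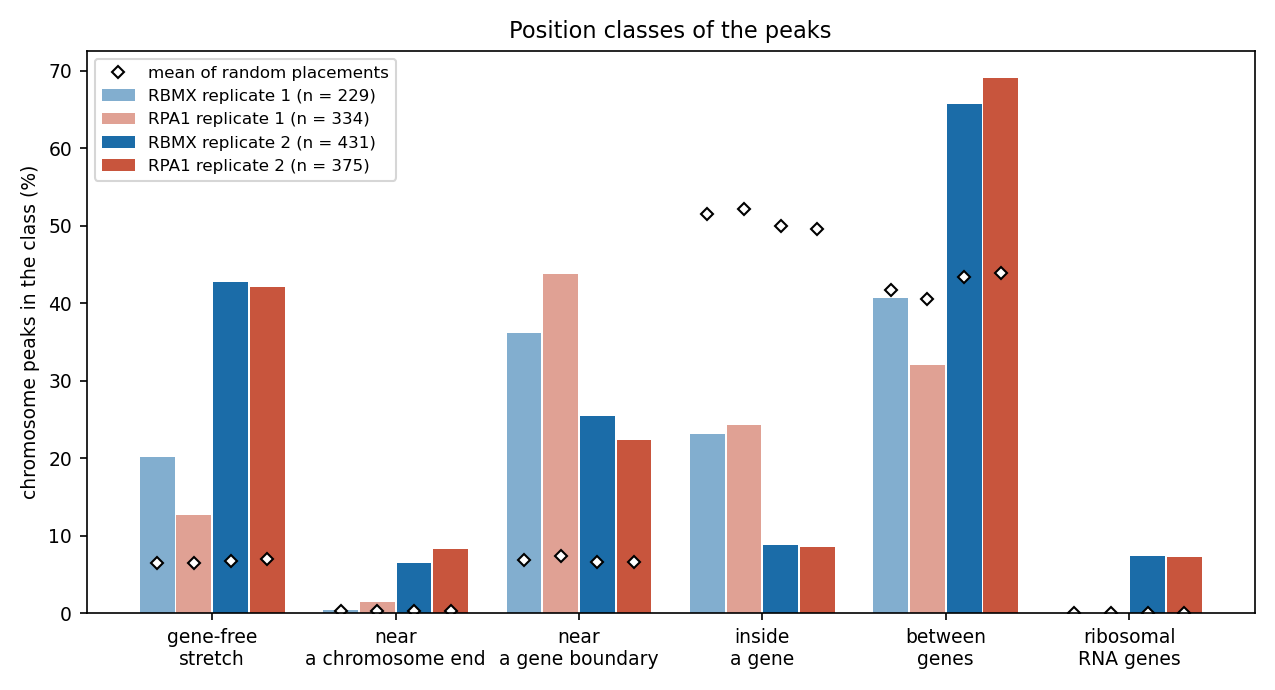
Share of the chromosome peaks of each list (vertical axis, %) in 6 position classes, with the mean of random placements as diamonds. Gene-free stretches held 42.7% and 42.1% of the replicate 2 peaks, and ribosomal RNA genes held 7.4% and 7.2% of them and none in replicate 1.

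Ribosomal RNA genes, whose tandem arrays supply the RNA of the ribosome, carried peaks of both proteins in replicate 2. RBMX peaks overlapped 24 and RPA1 peaks 21 of the 551 annotated genes of this list, and 32 RBMX and 27 RPA1 peaks lay there (permutation p = 0.0001 each, 0.0003 adjusted). All lay in the 5S array of chromosome 1 or the 45S units of chromosome 21. The test placed each peak independently, so these p-values count neighbouring peaks of the same array as separate hits. The list was made by the start of the gene symbol and was not limited to the arrays, so 551 is not their size. In the 5S array of chromosome 1, peaks of both proteins lay over RNA5S1 to RNA5S7, RNA5S10 to RNA5S14 and RNA5S17, with folds of up to 25.4 for RBMX and 23 for RPA1, and RNA5S8 had an RBMX peak. The region of this array held 23 RBMX and 29 RPA1 peaks, and that of the 45S units of chromosome 21 held 63 and 71. The 45S units of chromosome 21, RNA45SN1, RNA45SN2 and RNA45SN3, had maximal folds of 21.5, 24.1 and 18.9 for RBMX and 16.4, 20.5 and 14.4 for RPA1. Replicate 1 had peaks over 0 ribosomal RNA genes in both lists; the difference between the replicate numbers was not tested. Of the 429 chromosomal tRNA genes, 8 carried an RBMX peak and 6 an RPA1 peak in replicate 2, all in the cluster of chromosome 1 between 161448951 and 161471205, for instance TRG-GCC1-2 with a fold of 24.1 for RBMX and 12.9 for RPA1 (permutation p = 0.0001 for both lists). The peaks of this tRNA cluster were likewise counted as separate hits. TRG-CCC5-1 had a peak in RBMX replicate 1 and TRN-GTT2-2 in RPA1 replicate 1. The 22 mitochondrial tRNA genes all lay under the peak of the whole mitochondrial genome in replicate 2. As none of these peaks was compared with an input at its own position, they do not separate binding from copy number or mappability. Replicate 1 had a local background and replicate 2 had none. The absence of ribosomal RNA and mitochondrial peaks from replicate 1 therefore cannot be read as a lack of binding.

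Of the families from pericentromeric and duplicated sequence, genes of the DUX4 family had peaks in replicate 2. The whole list held 6 RBMX peaks (permutation p = 0.0113, adjusted 0.0233) and 8 RPA1 peaks (permutation p = 0.0003, adjusted 0.0008). Neighbouring peaks over the same gene were counted as separate hits here too. DUX4 on chromosome 4 had 3 RBMX peaks, with a fold of up to 91.8, and 4 RPA1 peaks, with a fold of up to 82.6. DUX4L9 and DUX4L26 had a peak of both proteins, DUX4L13 and DUX4L25 of RPA1 and GOLGA3 of RBMX, at the position of the ribosomal protein pseudogene RPS11P5 within it. Small nuclear RNA genes had peaks in replicate 1, with RNVU1-6 in both lists and RNVU1-14, RNVU1-15, RNVU1-27, RNVU1-30 and RNVU1-34 in that of RPA1. The count was above random placement for RPA1 (6 peaks, permutation p = 0.0001) and not for RBMX (1 peak, permutation p = 0.1708). Of 20 genes at common fragile sites, which break under replication stress, LRP1B had an RPA1 peak of replicate 1 with a fold of 7.4. The other 3 lists had 0 peaks over these genes. The histone pseudogene H2BC19P had a peak in RBMX replicate 1 and the mucin gene MUC3A in RPA1 replicate 1. Of 11 abundantly transcribed genes, EEF1A1 had a peak in all 4 lists and ACTB and GAPDH in both replicate 2 lists.

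RBMX and RPA1 were then compared for the kinds of sequence in their lists. In neither replicate number did any of 17 classes differ between the proteins at an adjusted p under 0.05 (Fisher's exact test, two-sided, Benjamini-Hochberg). At an unadjusted p under 0.05 there were 2 classes in replicate 1 and 0 in replicate 2. These were gene-free stretches, which held 20.1% of RBMX and 12.6% of RPA1 peaks (Fisher's exact test, p = 0.01815, adjusted p = 0.3085), and sequence between genes, with 40.6% and 32.0% (Fisher's exact test, p = 0.03951, adjusted p = 0.3358). In replicate 2 the shares in gene-free stretches were 42.7% and 42.1% (Fisher's exact test, p = 0.8866). Most replicate 2 peaks were shared, which by itself makes the 2 lists alike. Among the 142 RBMX and 66 RPA1 peaks of replicate 2 found in only 1 list of the pair, 3 classes had an unadjusted p under 0.05. The smallest adjusted p there was 0.127 (Fisher's exact test). A single class pooled RBMX, RBMXL1 and RPA1, so it can hide a difference between the proteins at these genes.

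The regions that set the 2 proteins apart in both replicates were over the genes that had been transfected. Of all merged regions, 4 were held by both RBMX lists and neither RPA1 list, and 2 by both RPA1 lists and neither RBMX list. All 6 lay over RBMX, copies of RBMX or RPA1. The RBMX gene (chromosome X, 136869192 to 136880725) had peaks with a fold of up to 8.9 in replicate 1 and 138 in replicate 2. RBMXL1 on chromosome 1, a protein-coding copy that also lies within KYAT3, had folds of 12 and 144.6, and the pseudogenes RBMXP2 on chromosome 9 and RBMXP5 on chromosome X had folds of up to 22.4 in replicate 1 and of 90.5 and 81.4 in replicate 2. RBMXP4 on chromosome 4 had a peak in RBMX replicate 2 with a fold of 27.4. RPA1 on chromosome 17, 1830005 to 1900082, had 9 peaks in RPA1 replicate 1 and 2 in RPA1 replicate 2, with folds of up to 17.6 and 21. The RPA1 lists had 0 peaks over RBMX and its 8 annotated copies, and the RBMX lists had 0 over RPA1. The copies RBMXP1, RBMXP3, RBMXL2 and RBMXL3 had no peak in any list. The RBMX copies other than RBMXL1 were chosen after their values were seen. Whether these peaks lie on exons was not analysed here.

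**Figure D4:**
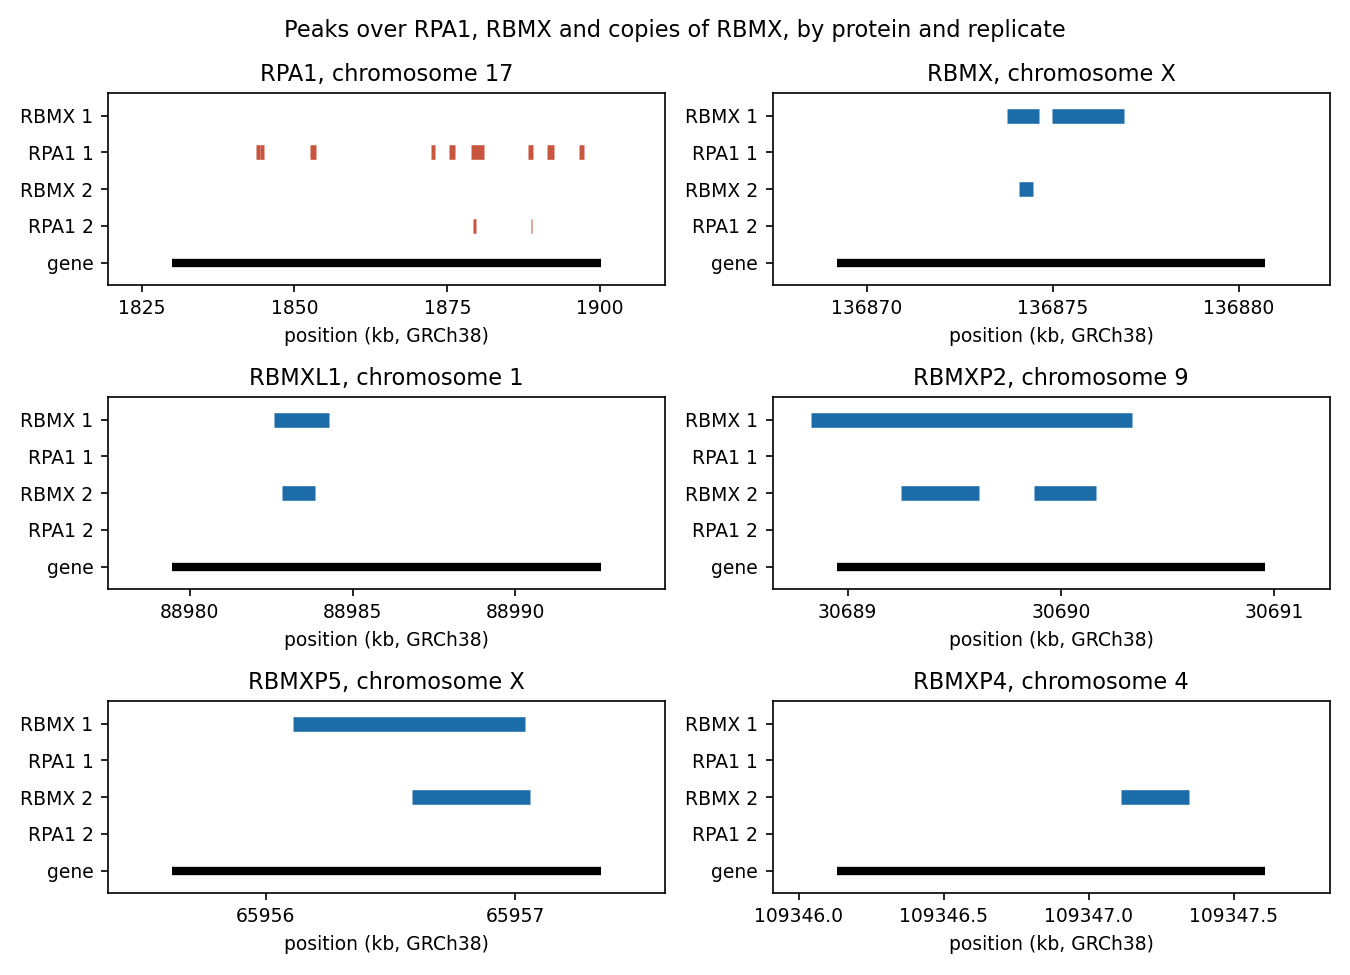
Peaks (coloured bars) of the 4 lists over RPA1, RBMX and 4 copies of RBMX, with the annotated gene as a black bar and position in kb of GRCh38 on the horizontal axis. RPA1 has 9 peaks in RPA1 replicate 1 and 2 in RPA1 replicate 2, and RBMX and its copies have peaks in RBMX lists alone.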

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

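The overlaps of whole lists and at the stricter threshold were planned; the comparison of the 100 peaks of largest fold was added after the data were examined and before its result was seen, and the other tests in this part, among them those of strong peaks against whole lists, were chosen after the results were seen.

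The share of RBMX peaks overlapping RPA1 peaks stood out because it was 34.8 percentage points higher in replicate 2 than in replicate 1, and the lists grouped by replicate number more than by protein. Thresholds may account for a part of that difference, which closed at a stricter threshold (52 of 65 peaks in replicate 1 against 456 of 598) and not among the 100 peaks of largest fold (65 against 95), and 77.4% and 66.1% of RBMX and RPA1 peaks of replicate 1 past that threshold were found in the other replicate. Among the 100 peaks of largest fold per list the mean share between proteins exceeded that between replicates by 41.2 points. This cannot decide on thresholds, because fold was relative to a local background in replicate 1 and to 1 genome-wide level in replicate 2. Against whole lists, partners in the other protein and in the other replicate were 100 and 37 for RPA1 replicate 2 and 95 and 49 for RBMX replicate 2. The replicate 1 cutoff was laxer in number, but its p-values were against a local background and those of replicate 2 against 1 genome-wide level. The cutoffs are therefore not on one scale, and these counts cannot decide on thresholds either. In replicate 1 the counts were 60 and 37 for RPA1, and 65 and 53 for RBMX, where the difference did not pass the test (exact McNemar test, p = 0.0576). Of these 100 peaks, 52 for RPA1 and 49 for RBMX reached a −log10 p of 10. The missing local background from an input also stays open. The divisor of the fold varied by 0.01325% in replicate 2, but the peak caller's settings fixed this, and neither replicate number had a local input. Replicate 1 had a local background from its own library and replicate 2 had none. The part of that difference in the grouping was not tested. Sequence of many copies that is also high in the inputs stays open, with 0 input lists analysed, and no biological explanation was tested.

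Copies of RBMX elsewhere in the genome stood out because 4 of 8 had a peak in an RBMX list and 0 had one in an RPA1 list. DNA of the expression construct may explain the peaks over RBMX and its copies: the 4 copies with a peak, RBMXL1, RBMXP2, RBMXP4 and RBMXP5, had it in RBMX lists only, of cells that received Flag-RBMX. The other 4 copies, RBMXP1, RBMXP3, RBMXL2 and RBMXL3, had none, and how like RBMX each copy is in sequence was not analysed here. The 9 peaks of RPA1 replicate 1 over the RPA1 gene were separate blocks between 1843767 and 1897323 on chromosome 17. Binding to the endogenous genes cannot be told apart from this for those 9 peaks, because the positions of exons and introns were not analysed here.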

How the results depend on the processing

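The local shift, the gene-free stretches and the strongest peaks against whole lists were chosen after the data were examined. Under alternative settings 102 values stayed the same, among them every overlap between lists and every comparison of folds run, not counting 16 values whose setting removed no peaks. Another 3 values moved, 3 reversed, 3 became weaker and 1 stronger. For tested values, the same means the same direction and side of the threshold. For untested counts and differences it means a change within set limits. Regions in 2 lists, for instance, went from 278 to 186 when merged within 1 kb. Without 1 replicate number the pooled overlap of 65.8% was 41.5% or 76.3%, and the count of classes that differ stayed at 0. The stricter threshold removed 193 RBMX and 286 RPA1 peaks of replicate 1 and 0 in replicate 2, where it tests nothing. Under it, the replicate 1 share near a gene boundary was 13.2% for RBMX and 11.9% for RPA1, no longer past the threshold. The share between genes turned from below to above random, at 75.5% and 67.8%, unplaced or alternate sequence rose to 18.5% and 20.3%, RPA1 peaks near a chromosome end were 1.7%, and regions in 1 list fell from 525 to 164, since fewer peaks were left. With 5 kb around gene boundaries, 35.4% of RBMX replicate 1 peaks lay between genes, slightly above random and not past the threshold. With 2 Mb at chromosome ends 5.7% of them passed it, against a random share that the limits of placement lower. The cause was not tested. Shifting all RBMX peaks by up to 50 kb, short unplaced sequences included, raised their random overlap with RPA1 to 10.01% in replicate 1 and 31.11% in replicate 2. Alternatives for repeats, tandem period, short motif and centromere distance were not run. No paired analysis was possible as a fit across samples, because the labels give only 1 replicate number and results come from peak lists; the McNemar tests pair peaks.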

Other observations

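All tests in this part were chosen after the results were seen.

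In replicate 2, pseudogenes were more frequent among RBMX peaks without an RPA1 partner than among shared RBMX peaks. They lay under 23 of 114 such RBMX peaks (20.2%) and under 16 of 317 shared RBMX peaks (5.0%; Fisher's exact test, two-sided, p = 9.835e-06), and under 4 of 49 RPA1 peaks without an RBMX partner (8.2%, p = 0.06783 against RBMX). Besides copies of RBMX they included the ferritin pseudogenes FTH1P7, FTH1P10 and FTH1P11 and the ribosomal protein pseudogenes RPL3P4, RPL10P16, RPL13P12, RPL18AP3, RPLP1P4, RPS11P5, RPS17P16 and RPS18P5, with folds between 11.1 and 17.0; these were named after their values were seen, and neither family was tested for enrichment. In replicate 1 the shares were 4.9% and 5.8% (Fisher's exact test, p = 0.767). Other regions, named after their values were seen, had peaks in both replicate 2 lists: ROCK1P1 on chromosome 18, with a fold of 107.4 for RBMX and 108.4 for RPA1 at 107861 to 109419, and the DANT1 and DANT2 locus on chromosome X, with folds of up to 28.7 and 17.9.

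RPA1 stood higher than RBMX at the outermost sequence of chromosomes in replicate 2. There were 11 such RPA1 peaks and 7 RBMX peaks, and the 7 shared positions, on chromosomes 5, 10, 12, 18, 22, X and Y, had a median log2 ratio of RPA1 to RBMX summit tags, each relative to its library size, of 1.42, higher for RPA1 in 7 of 7, as it was in 305 of the 428 other shared regions (71.3%). The tables argue against an RPA1 library that is higher everywhere, since the other shared regions had a median of 0.14 and a maximum of 1.44 (difference 1.28, two-sided permutation p = 1e-05, the smallest possible). That test treats the positions as independent, but sequence shared between chromosome ends was not analysed here. The X and Y positions had 95 and 89 RBMX tags and 245 and 247 RPA1 tags at the summit. Whether they are separate signals is unknown. More telomeric DNA in the cells or library before precipitation stays open, with 0 input lists analysed. RPA1 bound to telomeric DNA may also give this, but RPA1 replicate 1 had 0 outermost peaks, as had RBMX replicate 1, so whether those lists could hold them is unknown.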
